A study of Homo sapiens with 24 samples.

How the data were processed

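Myc CUT&Tag was measured in MIA PaCa-2 cells with doxycycline-inducible MED30, in 1 library without doxycycline and 1 titled as day 5. Samples were grouped by their titles. The remaining 22 of the 24 samples of the series, which cover other Myc, Mediator, histone mark and IgG libraries, were not analysed here. Per the labels' protocols, cells were lightly fixed for non-histone targets, and the doxycycline time is given as 2 days, unlike the 5 days of the title.

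Per the submitters' processing notes, Trim Galore, Bowtie2, deepTools and MACS2 were used with build hg38; their versions and settings are not given in the sources used here, nor is whether an IgG control entered the peak calls. Each deposited list has 10 columns, with peaks called per library and no sign of pooling. The deposited score of a peak is the integer part of 10 times its −log10 q-value. The fold that the authors deposited is the enrichment at the summit over the caller's local background in that library, a ratio. The authors also deposited the −log10 p-value and −log10 q-value at the summit, with a smallest −log10 q-value of 1.33 in both lists, and the offset of the summit from the peak start in bp. These values are not comparable between libraries of unequal depth, so no peak's value was compared between lists. Classes of −log10 q used the same limits in both lists, where equal values need not mean equal strength. The deposited values served to rank, class or filter peaks within a list and to recover fragment numbers.

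The lists held 3559 and 6953 peaks in all, and comparisons used the 3472 and 6727 on chromosomes 1 to 22, X and Y. Total reads are not in the lists, so depth was read from the peaks. The deposited fold and −log10 p-value together give the number of fragments over the summit and the local background, when fold is (fragments + 1)/(background + 1) and p is a Poisson tail. Whole numbers of fragments were recovered, within 0.001 in −log10 p, for 99.9% of peaks without doxycycline and 99.97% at day 5. The steps of the background gave fragment lengths of 345.2 and 342.5 bp. Fragments flanking a summit were taken from the background over 10 kb less those at the summit, so they include the rest of the peak and any other peak in that window. PCR duplicates cannot be seen in peak lists, so intervals of fragment numbers cover counting error only.

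Gene spans came from the NCBI RefSeq annotation of GRCh38.p14, which is the hg38 assembly, without strand, exons or sequence. Planned promoter windows were therefore replaced by windows of 1 kb around either end of a gene span, for 20033 protein-coding genes. Planned matching of random gene lists on promoter GC content was replaced by matching on span length in 10 bins, and planned counts of the CACGTG motif were not made. Lists were compared by overlap of at least 1 bp, beside 1000 random placements of peaks within their chromosomes. Shares have exact Clopper-Pearson intervals and fragments exact Poisson intervals at 95%. The 28 gene lists, of which 2 of 956 symbols had no match, were set beside 10000 random lists as a description of these 2 libraries, with no p-value. Gains at day 5 were set beside genes with peaks of like rank, in 10 bins.

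Named genes followed a rule set, like the gene lists and most of the alternative settings, before the data were examined: the 10 genes with the highest-ranked peak in both lists, at day 5 only and without doxycycline only; up to 4 members of each gene list with the highest-ranked day 5 peak, and members listed only without doxycycline; and MED30, MYC, MAX, NCL, ODC1, CDK4, LDHA, NPM1 and CDKN2A. The nearest gene end to the summit decided which gene a peak named, by the day 5 peak where there was one, except for the fixed genes and the list members listed only without doxycycline. The value given for the library without doxycycline is that of a peak within 1 kb, which for MVK lay nearer another gene. Counts per gene and per list took any peak within 1 kb. From each gene list the text names a selection.

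Alternatives were the upper part of each list by rank, all chromosomes and contigs, reciprocal overlap of 50%, summits within 500 bp, merging of peaks within 500 bp, equal numbers of peaks, gene-end windows of 500 and 2500 bp, and unmatched random lists. Added after seeing the data was thinning of the day 5 summits by the ratio of flanking fragments, taken as a stand-in for depth. It used 100 draws, with its bounds written before its own result. Leaving out chromosome ends (50 kb) and a cluster of peaks at 629 to 635 kb of chromosome 1 was also added then. The recovery of summit fragments was tested on simulated data, with 100% recovered in lists of 3472 and 6727 simulated peaks, as were 100% of planted overlaps and 100% of 200 planted genes. In a simulation of 5000 sites, 2581 were called at the lower depth, 3178 at 1.5 times that depth and 2523 after thinning back. It thinned by the known depth ratio against a known background and asked for no smallest width. It therefore checks only the arithmetic of thinning, not its use on these lists. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.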

Results

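Myc binding was profiled by CUT&Tag, in which an antibody bound to its target brings a transposase that cuts and tags the DNA around it, so that bound sites appear as peaks of sequenced fragments. The cells were MIA PaCa-2, an established human pancreatic carcinoma line, carrying a doxycycline-inducible MED30. MED30 is a subunit of Mediator, the complex that connects transcription factors to RNA polymerase II. The series design asks how extra MED30 influences the binding of other factors. Of its 24 samples, the deposited Myc peak lists of 2 were used: 1 library without doxycycline and 1 titled as day 5 of doxycycline. The other 22, among them a Myc library at day 1 and libraries made with control IgG, were not analysed here. Peaks that control IgG would also give were not removed here, so a Myc peak means a peak of the Myc library, and some can be background. The shared protocol in the labels speaks of 2 days of doxycycline, and the day in the title was followed. Total read numbers per library were not given in the sources used here. The median peak had 11 fragments over its summit without doxycycline (quartiles 8 and 15) and 12 after it (8 and 17), and 42.2% and 34.8% of peaks had fewer than 10. With 1 library per condition, none of the differences below has a replicate check, and each one compares these 2 libraries. Intervals are exact binomial (Clopper-Pearson) or exact Poisson 95% intervals, except where a bootstrap is named. Poisson intervals cover the counting error of fragments only, and binomial intervals treat peaks or genes as independent draws. None covers the spread between replicate libraries.

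The first question was where Myc was found with and without doxycycline, which was given to induce MED30. Most of the strongest Myc sites were in both lists. Those at gene ends included DDX42, an RNA helicase of the splicing machinery, ZNF131, a zinc finger protein, DUS3L, a tRNA-modifying enzyme, and CCT3, a subunit of the chaperonin that folds actin and tubulin. On chromosomes 1 to 22, X and Y the list without doxycycline held 3472 peaks covering 1982 kb, and the list at day 5 held 6727 peaks covering 4327 kb, 1.94 times as many. Thinned by the ratio of fragments flanking shared peaks, day 5 kept 1.47 times as many peaks. When the smallest listed width was also asked for, it kept 0.931 times as many. Of the peaks without doxycycline, 2853 (82.2%, interval 80.9 to 83.4) overlapped a day 5 peak by at least 1 bp, against a mean of 12.6 and a maximum of 26 over 1000 random placements. Here and below, random placement took any position of the chromosome, without regard to genes. An excess over it is therefore not shown to be particular to Myc. Of the day 5 peaks, 3878 (57.6%, 56.5 to 58.8) had no counterpart without doxycycline, whereas 619 peaks (17.8%) of the other list had none at day 5.

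The −log10 q, fold and score of each peak are the authors' own values, and peaks were ranked by −log10 q within each list. Ranked this way, the overlap followed peak strength in both libraries. Among peaks with a −log10 q of at least 20, 172 of 173 without doxycycline and 359 of 378 at day 5 (interval 92.3 to 96.9%) had a counterpart. Below a −log10 q of 3 the shares were 56.6% (52.4 to 60.7) and 12.1% (10.1 to 14.4). The shares are to be read within each library. Equal −log10 q need not mean equal strength in both, and the lists searched for counterparts held 6727 and 3472 peaks. Peaks without a counterpart had a median of 7 summit fragments without doxycycline and 9 at day 5, and peaks with one had 12 and 17. When only the 3472 highest-ranked day 5 peaks were taken, 62.2% of the peaks without doxycycline had a counterpart. At the 2849 shared peak pairs the fragments flanking the summit were 1.75 times as many at day 5 (95% bootstrap interval 1.72 to 1.77). These flanks also hold the rest of the peak and any other peak in the 10 kb window. The ratio therefore does not separate background coverage or depth from signal.

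**Figure D1:**
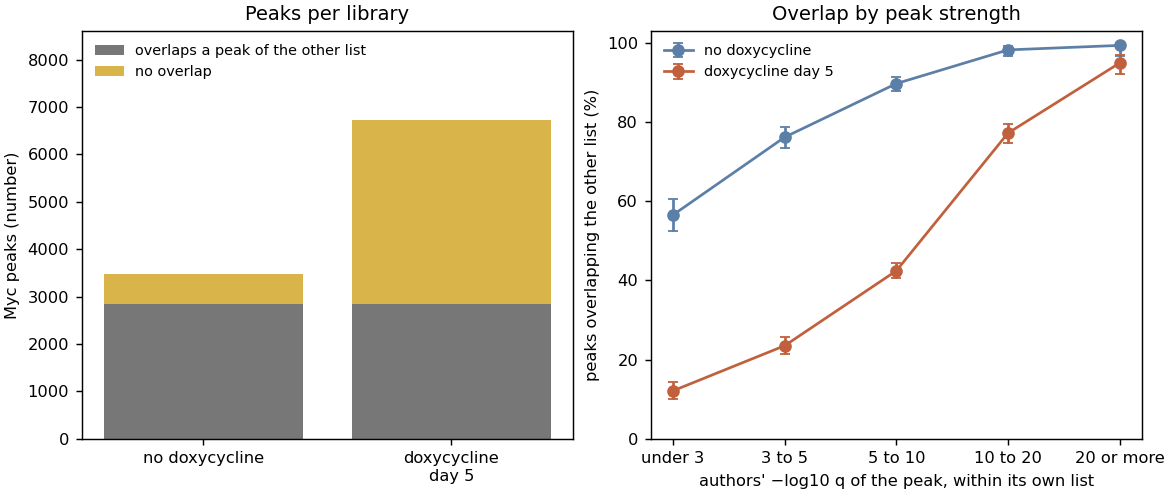
Left, the number of Myc peaks in each library, with the 2853 and 2849 peaks that overlap the other list in grey and the remaining 619 and 3878 in yellow. Right, the percent of peaks overlapping the other list in 5 classes of the authors' −log10 q, with exact 95% binomial intervals as bars; the share climbs from 56.6% to 99.4% without doxycycline and from 12.1% to 359 of 378 peaks at day 5.

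Myc lay mostly beside genes in both libraries. Within 1 kb of an end of a protein-coding gene were 66.2% of peaks without doxycycline (64.6 to 67.7) and 66.5% at day 5 (65.4 to 67.6), against 3.73% and 3.84% after random placement. Elsewhere inside protein-coding genes lay 14.8% and 15.8% of peaks, inside other annotated genes 6.71% and 5.95%, and outside annotated genes 12.3% and 11.7%. Shared peaks were at gene ends in 70.1% and 70.4% of cases. Of the peaks listed only at day 5, 63.6% (62.1 to 65.1) were at gene ends, and of those listed only without doxycycline, 48.1% (44.1 to 52.2). The annotation used gives no strand, so the start and the far end of a gene were not told apart, and exons and introns were not separated.

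Per gene, 2894 of 20033 protein-coding genes (14.4%) had a Myc peak within 1 kb of an end without doxycycline, and 5484 (27.4%) had one at day 5. Both lists held 2580 of them, where independent lists of these sizes would share 792. That number treats all genes alike, so the excess is not shown to be particular to Myc either. The genes with the highest-ranked day 5 peak among those in both lists were DDX42 (chromosome 17, gene span 63773800 to 63819317 in hg38) with 74 fragments over the summit without doxycycline and 116 at day 5, ZNF131 with 82 and 117, DUS3L with 83 and 93, and GOLIM4, a Golgi protein, with 73 and 96. Next came SEH1L, a nuclear pore protein, with 58 and 95, CIC, a transcriptional repressor controlled by MAP kinase signalling, with 61 and 86, and SNX8, a sorting nexin, with 63 and 96. The uncharacterised LOC124904276 had 81 and 99, CCT3 72 and 81, and NRL, a retinal transcription factor, 60 and 83. Each peak was given to the gene whose end lay nearest its summit, and a neighbouring gene that shares the region is not excluded.

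A Myc peak was listed at day 5 only for 2904 genes. The highest-ranked were ZNFX1, a helicase-like zinc finger protein (chromosome 20, peak 49278069 to 49278656, 59 fragments), COL5A2, a fibrillar collagen chain (36), and ARMC5 (46). PPA1, the cytosolic pyrophosphatase, had 35 fragments, PABPC1, the cytoplasmic poly(A)-binding protein, 37, and SLC20A1, a phosphate transporter, 42. CCDC61 had 32, REPIN1 41, FRAT2, a Wnt pathway protein, 33, and APBB3 30. A peak was listed only without doxycycline for 314 genes. TPX2, a spindle assembly factor (chromosome 20, peak 31738784 to 31739197), had 16 fragments, ZMYM6 16, FUZ 17, ASH1L, a histone methyltransferase, 18, and THAP1 13. TUBB3, a beta-tubulin, had 23, TENT2, a poly(A) polymerase, 13, DOHH, the second enzyme of hypusine formation, 14, LCMT2 12 and PHRF1 12. With equal numbers of peaks the genes at day 5 were 3146, or 1.09 times those without doxycycline, in place of 1.89 times. A gene missing from a list has no peak past the authors' threshold, which does not show that Myc is absent from it.

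Genes of protein synthesis carried Myc peaks far more often than random genes of like length, in both libraries. Here and for the lists below, the random genes came from all 20033 protein-coding genes, matched on neither activity nor promoter GC content. An excess over them is therefore not shown to be particular to Myc. Of 79 cytosolic ribosomal protein genes, 44 (55.7%, 44.1 to 66.9) had a peak without doxycycline and 59 (74.7%, 63.6 to 83.8) at day 5, where 10000 random lists matched on gene length averaged 10.3 and 18.7. RPS14 had 42 and 43 summit fragments and RPS19 32 and 41, and RPL23, RPL24 and RPS20 were listed only without doxycycline. Of 60 ribosome biogenesis genes, 30 and then 48 had a peak. UTP18 had 67 and 62 fragments, DKC1, the pseudouridine synthase of box H/ACA particles, 25 and 53, and DDX21 48 and 48. Mitochondrial ribosomal proteins had 25 and 44 of 75 (MRPL48 with 40 and 37 fragments), and translation factors 22 and 34 of 44 (EIF5A with 61 and 66). RNA polymerase I and III genes had 15 and 22 of 33, led by POLR3D with 28 and 52 fragments. In these 5 lists 0 of 10000 random lists held as many genes in either library. Aminoacyl-tRNA synthetases had 18 and 21 of 37, reached by 0 and 5 random lists, with TARS1 at 28 and 52 fragments.

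Metabolic lists stood above random lists too. Nucleotide synthesis had 17 and 21 of 30 genes, with CTPS1, the CTP synthase, at 35 and 56 fragments and PPAT, which commits to purine synthesis, at 47 and 62. Mitochondrial import, chaperone and respiratory chain genes had 25 and 34 of 40, with HSPA9 at 54 and 57 fragments and HSPD1 at 14 and 43. In both lists 0 of 10000 random lists held as many in either library. Serine, one-carbon and polyamine metabolism had 7 and 12 of 20 (197 and 25 random lists as high), with MTHFD2 at 25 and 43 fragments. Glycolysis had 8 and 15 of 23 (200 and 3), with GAPDH at 29 and 62 fragments and ENO1 at 13 and 51. Cholesterol synthesis had 8 and 13 of 23 (322 and 141), with MVK at 14 and 28 fragments. The unfolded protein and integrated stress response had 8 and 14 of 26 (228 and 19), with HERPUD1 at 38 and 44.

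The Myc network itself had 12 and 15 of 30 genes with a peak (8 and 102 random lists as high). MXD3, a Max partner that represses, had 13 and 53 fragments, MXD1, another, 20 and 34, and AURKA, CCNT1, RUVBL2 and SKP2 were listed only without doxycycline. Cell cycle and DNA replication genes had 9 of 44 without doxycycline and 24 at day 5 (2532 and 2 random lists as high), among them CDK4, POLD1, AURKB and MCM3. Mediator subunits had 7 and 14 of 33 (2307 and 577). CDK19 had 17 and 32 fragments and MED11 35 and 36, MED19 and MED20 were listed only at day 5, and MED31 only without doxycycline. Core clock genes had 7 and 9 of 18 (97 and 387), with PER3 at 15 and 35 fragments. Cell cycle inhibitors and p53 targets had 7 and 13 of 30 (1469 and 504), with PLK3 at 29 and 41. Lysosome and autophagy genes had 8 and 20 of 40 (3067 and 65), the hypoxia response 4 and 10 of 20 (3460 and 304), and immediate early genes 4 and 13 of 35 (7240 and 813), with EGR1 at 14 and 26 fragments. Histone genes of the replication clusters had 4 and 14 of 50 (5659 and 74), a day 5 figure that became 5189 when the random lists were not matched on length; histone genes are short, near-identical and densely packed, so 1 peak can serve several.

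Mesenchymal and epithelial genes had about as many peaks as random genes, 2 and 6 of 24 (8662 and 6430 random lists as high), among them VIM, ZEB1 and ESRP2. Lists of other cell types had few or none. Interferon and antigen presentation genes had 1 and 2 of 35, TRIM25 in both and MX1 at day 5, and 226 and 7 of 10000 random lists held as few. Peaks on alternate haplotypes of the major histocompatibility region, 30 and 87 in number, were not assigned to these genes. No gene of the acinar and endocrine pancreas list (29), the hepatocyte list (22) or the keratin and skin barrier list (20) had a peak in either library. Of 20 neuron markers only SNAP25 had one, at day 5, and of 21 leukocyte markers CD8A had one in both and CD4 at day 5. In 25 of the 28 lists more genes had a peak at day 5, and in the other 3 none had one in either library. With equal numbers of peaks 13 lists had more genes at day 5, 8 as many and 7 fewer, so the direction for single lists depended on the number of peaks taken. Equal numbers also left more random lists as high at day 5 for several lists: 573 for the cell cycle, 558 for the clock, 1536 for lysosome and autophagy and 3428 for histones. The figure was 4368 for hypoxia, 1205 for cholesterol synthesis, 6374 for Mediator subunits, 1043 for cell cycle inhibitors and p53 targets and 1395 for immediate early genes. RNA polymerase I and III rose from 0 to 84, glycolysis from 3 to 96 and the unfolded protein and integrated stress response from 19 to 100. Fewer random lists were as high for the Myc network (51) and for serine, one-carbon and polyamine metabolism (1). The same held for mesenchymal and epithelial genes (5121), interferon and antigen presentation (9985) and leukocyte markers (9726). Against random genes with day 5 peaks of like rank, lysosome and autophagy showed the lowest count of draws with as many newly listed genes (14 of 20 against 11.1, with 1120 of 10000 draws as high). Mitochondrial import, chaperones and respiratory chain showed the lowest count of draws with as few (9 of 34 against 14.9, with 91 of 10000 draws as low), among 25 lists compared.

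**Figure D2:**
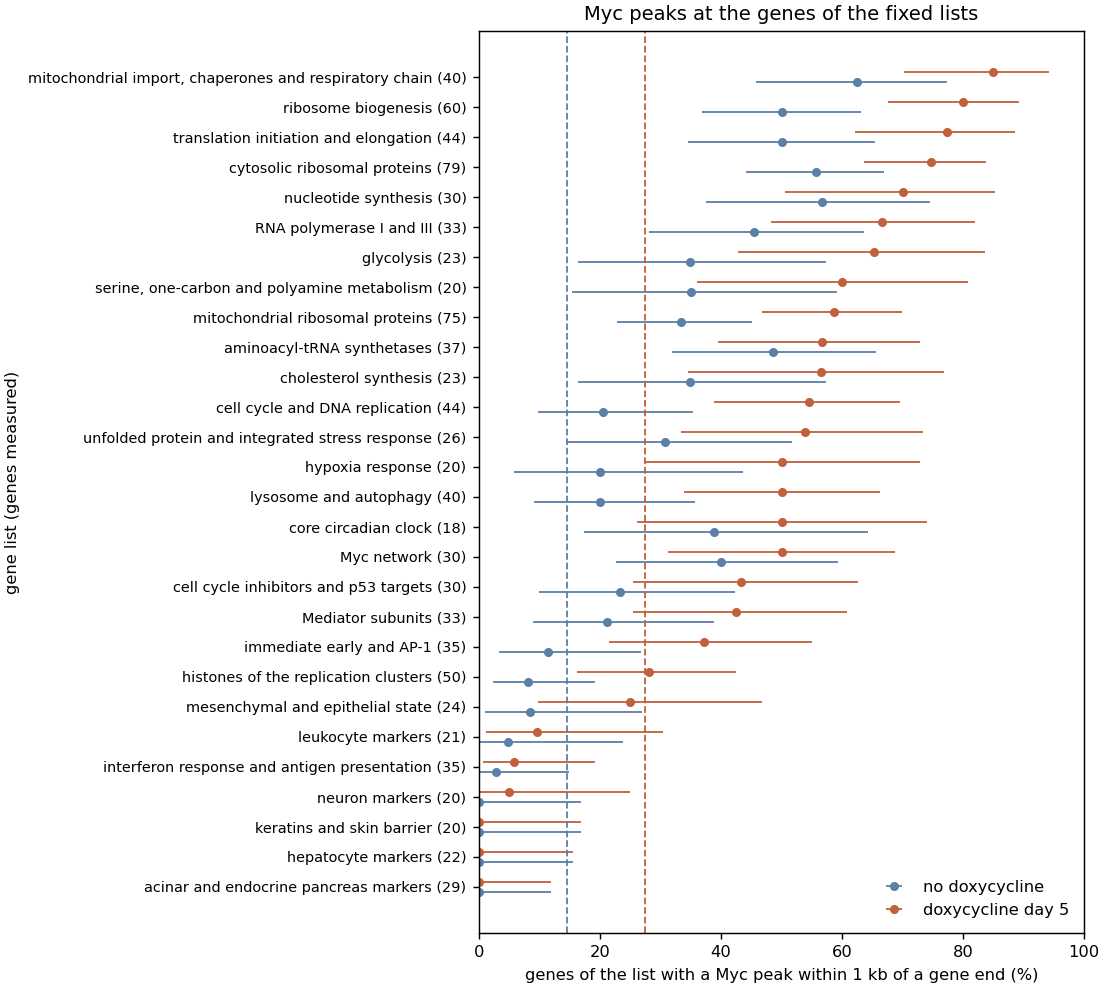
The percent of each gene list with a Myc peak within 1 kb of a gene end (horizontal axis) without doxycycline (blue) and at day 5 (orange), with exact 95% binomial intervals as bars and the number of genes in brackets. Dashed lines mark all protein-coding genes, 14.4% and 27.4%; cytosolic ribosomal proteins lie at 55.7% and 74.7%, and the pancreas, hepatocyte and keratin lists at 0.

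The MYC gene itself carried a Myc peak in both libraries. In hg38 its span is 127735434 to 127742951 on chromosome 8, and the peak lay at 127735192 to 127735874 without doxycycline with 12 fragments (exact Poisson interval 6.2 to 21) and at 127735178 to 127736089 at day 5 with 27 (17.8 to 39.3). Between 127253442 and 128344165 there were 4 peaks without doxycycline and 7 at day 5, 3 of them shared. MAX, the partner of Myc on DNA, had 13 (6.9 to 22.2) and 25 (16.2 to 36.9) fragments, CDK4 13 (6.9 to 22.2) and 23 (14.6 to 34.5), and NPM1, a nucleolar chaperone, 24 (15.4 to 35.7) and 45 (32.8 to 60.2). NCL, nucleolin, had 45 (32.8 to 60.2) and 53 (39.7 to 69.3), and LDHA, lactate dehydrogenase A, 23 (14.6 to 34.5) and 19 (11.4 to 29.7). ODC1, the first enzyme of polyamine synthesis, had a peak only at day 5, with 15 (8.4 to 24.7). All intervals of the pairs overlapped, which is not a test of equal counts, and the fragments flanking shared peaks differed by 1.75 times. MED30 (chromosome 8, 117520713 to 117540262) had no peak in either library, the nearest lying 754 and 646 kb away, and Myc peaks do not measure how much MED30 was made. CDKN2A (chromosome 9, 21967752 to 21995324) had none either, and no peak was listed over the surrounding 7576 kb without doxycycline or 7512 kb at day 5. Peak lists do not show whether a stretch without peaks was covered by reads or is present in these cells.

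**Figure D3:**
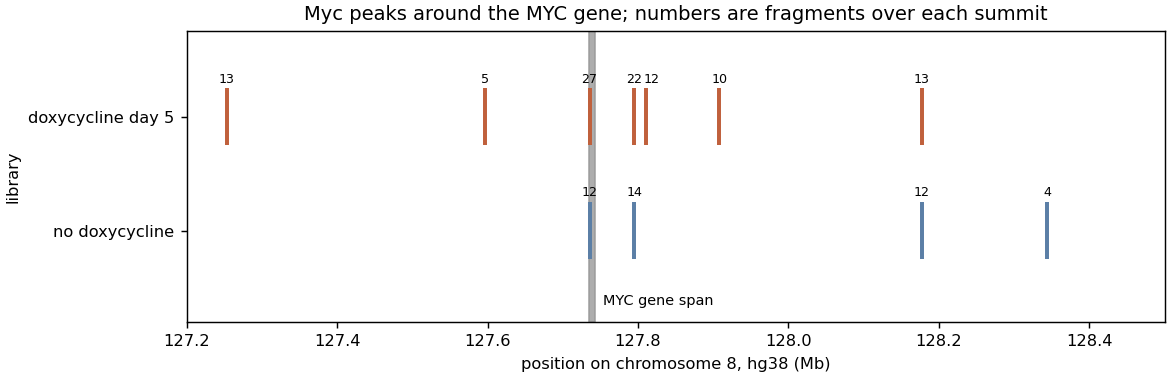
Myc peaks around the MYC gene on chromosome 8 (horizontal axis, Mb in hg38) in the 2 libraries, with the fragments over each summit as numbers and the MYC span in grey. Each bar marks the centre of a peak and not its width; 3 peaks are in both libraries, the one at MYC with 12 and 27 fragments.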

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

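These peaks lie on sequences that the main comparisons left out, and no test was chosen for their number. The mitochondrial genome carried 5 peaks without doxycycline and 3 at day 5. Contigs outside the primary chromosomes carried 82 peaks without doxycycline and 223 at day 5. Of these, 30 and 87 lay on alternate haplotypes of the major histocompatibility region on chromosome 6, where the primary chromosome, which the comparisons do cover, carried 4 and 16.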

How the results depend on the processing

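Settings added only after the results were seen were thinning and leaving out chromosome ends with the chromosome 1 cluster. The ratio of peaks ran from 1.47 after thinning by the flanking ratio (1.65 by the summit ratio) to 1.95 with contigs, and was 0.931 only in thinning by the flanking ratio that also asked for the smallest listed width. Taking the upper part of each list by rank left 1736 and 3369 peaks, 1088 and 2475 kb covered, and 1607 and 3074 genes without doxycycline and at day 5, by its own construction. The overlapping share without doxycycline became 67.1% with reciprocal overlap, 79.1% with summits within 500 bp and 62.2% with equal numbers of peaks, and at day 5 it became 34.6%, 40.8% and 62.0%, and 48.9% after thinning. Gene-end shares were 62.3% and 63.2% with 500 bp windows, 70.0% and 70.1% with 2500 bp windows, and 72.5% at day 5 with equal numbers. Equal numbers also gave 3146 genes at day 5 and a gene ratio of 1.09. They turned the direction of 7 gene lists, with day 5 minus no doxycycline at -3 for RNA polymerase I and III, -3 for aminoacyl-tRNA synthetases, -3 for mitochondrial import, chaperones and respiratory chain, -2 for Mediator subunits, -1 for the Myc network, -1 for the clock and -1 for cholesterol synthesis; the cause was not tested beyond the smaller number of peaks. No list turned under the 4 other settings run on lists. Random lists not matched on length had as many day 5 genes in 445 draws for Mediator subunits, 452 for cell cycle inhibitors and p53 targets and 5189 for histones, in place of 577, 504 and 74. The 3 alternative settings on the CACGTG motif were not run, as no genome sequence was used here. No paired analysis was possible because replicate numbers in the labels are shared only by MED1 and MED30 libraries not analysed here, and each Myc condition had 1 library. Depth limits the weakest calls, which rest on as few as 3 fragments.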

Other observations

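The gene families and all tests in this part were chosen after the peak lists had been seen, and only the bounds for thinning by the flanking ratio, with no limit on width, were written before the result of that thinning. Beyond the lists fixed beforehand, Myc peaks were frequent at the folding and degradation machinery. The chaperonin containing TCP1 had a peak at 7 of 9 genes without doxycycline and 8 at day 5, reached by 2 and 6 of 10000 random lists. Proteasome subunits had 13 and 18 of 39 (41 and 139 random lists as high), led by PSMC4 and PSMD9. Complex I subunits had 12 and 22 of 36 (50 and 0), led by NDUFA11, and the small nuclear ribonucleoproteins of the spliceosome 8 and 15 of 23 (242 and 2), led by SNRPA. Zinc finger genes named ZNF had 91 and 181 of 509 (2043 and 84). Solute carriers had 48 and 90 of 347 (8234 and 9371). With equal numbers of peaks the day 5 counts were 8 for the chaperonin, 10 for the proteasome and 12 for complex I. They were 10 for the ribonucleoproteins, 102 for genes named ZNF and 48 for solute carriers. No peak was listed in either library at 392 olfactory receptors, 94 keratin-associated proteins or 39 beta-defensins.

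Myc peaks also lay beside genes of small RNAs. Of 429 tRNA genes, 81 (18.9%) had a peak within 1 kb of an end without doxycycline and 125 (29.1%) at day 5, 66 of them in both, where random placement of the day 5 peaks gave a mean of 2.8. Small nuclear RNA genes had 24 and 40 of 154. Of 1199 small nucleolar RNA genes 31 (2.59%) and 40 (3.34%) had a peak, and of 1913 microRNA genes 43 (2.25%) and 92 (4.81%). These shares lay under those of protein-coding genes, 14.4% and 27.4%. Random placement of the day 5 peaks gave means of 7.75 and 13.9. Pseudogenes had 48 and 91 of 15580, with a day 5 random mean of 125, and long non-coding RNA genes 796 and 1513 of 18303, with 219.5. Many tRNA genes are clustered, so 1 peak can serve several.

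The day 5 list held 1.94 times as many peaks. Whether enrichment over background was sharper could not be decided. At 354 strong shared pairs the summit ratio over the flanking ratio was 0.868 (95% bootstrap interval 0.831 to 0.906), so summits rose less than flanks. The flanks hold the rest of the peak beside its summit, so wider peaks would also lower this ratio. Greater nuclear read depth stays open: thinning day 5 summits by the flanking ratio of 1.75 left 5120 ± 26 peaks (SD, 100 draws), 1.47 times the other list and above the bound written before it. That bound left out the smallest listed width of 345 bp, about the fragment length, and further draws, made after that result, that also asked for this width under an assumed triangular summit left 3233 ± 34, or 0.931 times. A smaller mitochondrial share may have gone with it, as mitochondrial background at day 5, read from 1 peak per library, was 0.572 times that without doxycycline, or 0.328 times relative to nuclear flanks (0.210 at the lowest over the 3 and 2 recovered backgrounds). Induced MED30 itself cannot be told apart from a difference between libraries, with 1 library per condition. Nor can it be told apart from doxycycline itself, since the series holds no Myc library of treated cells without inducible MED30.

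Within 50 kb of chromosome ends the day 5 list held 14 peaks on 11 chromosomes and the other list 2, where random placement gave 5.23 and 2.70. Of the day 5 peaks, 12 had no counterpart, and they made up 5 of the 19 such peaks with a −log10 q of at least 20. At the chromosome 5 end, listed in both, 10 and 155 fragments gave a ratio of 15.5 (exact 95% interval 8.21 to 33.0), which depth with its flanking ratio of 1.75 does not reach. Whether depth was the whole cause for the end peaks as a set stays open. Thinned by the flanking ratio, 11 of the 12 (91.7%) passed in most draws, past the bound written before against depth. That bound left out the smallest width. When this width was asked for, 5 of the 12 passed in most draws, on the side of depth by the bounds written before. Of all 14, 3 to 11 (mean 7.23) were then kept per draw, against 2 listed without doxycycline. The end peaks were picked after the lists had been seen. Reads of a repeat placed at several ends could also give peaks on 10 chromosomes at once, which sequence would decide, and a biological gain at day 5 stays open, untested.

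Peaks listed only without doxycycline could be calls near the detection limit. Of the 868 highest-ranked peaks of that list, 19 (2.19%) had no day 5 counterpart, against 340 (39.2%) of the 868 lowest-ranked. Loss of Myc from such sites with induced MED30 stays open and untested, with 1 library per condition.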
